A study of Mus musculus with 20 samples.

How the data were processed

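The series holds poly(A) RNA of mouse heart tissue, extracted with Trizol. Short-read Illumina libraries were made for 4 groups of 4 libraries each: myocardial infarction (MI), its sham operation (MISham), ischemia-reperfusion (IR) and its sham operation (IRSham). Per the labels, the MI and MISham tissue took in the infarct core and the area around it, and the IR and IRSham tissue came from the core alone. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries. There were 4 further long-read Nanopore libraries, 1 per group, which the submitters used to find unannotated transcripts and genes; the deposited tables hold no values for them, and they were not analysed here.

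The deposited gene table holds raw counts for each library, whole numbers with no normalization. The deposited transcript table holds TPM, transcript abundances scaled to one fixed sum, for each library. The authors' processing notes name HISAT2 2.2.1, SAMtools 1.7, featureCounts 2.0.1, kallisto 0.50.1 and the GRCm39 genome, without the role of each tool, the strand setting or the annotation release. The count table lists 63318 genes, of which 53633 carry Ensembl IDs and 9676 carry IDs that mark them as not in the reference annotation; 1440 of the latter are antisense to an annotated gene, and 9 IDs join 2 annotated genes. Since the strand setting is not given in the sources used here, counts of genes that overlap on opposite strands cannot be separated. The TPM table lists 163740 transcripts, 140670 with Ensembl IDs and 23070 with long-read IDs. Symbols and biotypes were looked up by ID in GENCODE M21, which gave a symbol for 52080 genes and a gene for 138330 transcripts; transcripts with long-read IDs are not paired with a gene in the files. GENCODE M21 is built on GRCm38 and the files on GRCm39, so no coordinates were used. The 2 columns of the transcript table with estimated counts and effective lengths name no sample and were not used here.

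Genes were tested in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15, and a robust quasi-likelihood fit with 1 mean per group over all 16 libraries. Adjusted p-values of genes come from edgeR's quasi-likelihood test with the Benjamini-Hochberg correction over 19741 genes, and a gene was called at an adjusted p under 0.05. CPM, counts scaled to the library total, are TMM-scaled. The standard error (SE) of a log2 fold change was derived from the fold change and its test statistic. The contrasts were MI against MISham, IR against IRSham, the difference of these 2 responses, and MISham against IRSham. Transcripts with a mean TPM of at least 1 were tested with limma 3.58.1 (moderated test with a trend) on log2(TPM + 1), with the same contrasts and threshold. Transcript usage is the share of a gene's summed TPM held by each transcript, in percent. A gene's summed TPM adds only the Ensembl transcripts matched to it, so every share is of annotated TPM. It was tested with limma for genes with a mean summed TPM of at least 5 and at least 2 transcripts with a mean share of at least 5%, and called at an adjusted p under 0.05 with a change of at least 10 percentage points. The unannotated transcripts enter the transcript test but not the usage test, because the files do not give their gene.

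The 32 gene lists were written before the data were examined, as were the tests, the thresholds, the rule for named genes and most of the alternative settings. The lists covered cardiomyocyte sarcomere, cardiac calcium handling and ion channels, cardiac stress and fetal genes, fatty acid oxidation, the nuclear-encoded mitochondrial respiratory chain, glycolysis, extracellular matrix and myofibroblasts, resident fibroblasts, monocytes and macrophages, neutrophils, lymphocytes, inflammatory cytokines and chemokines, interferon-stimulated genes, cell cycle, hypoxia-inducible genes, the NRF2 response, the unfolded protein response, apoptosis, pyroptosis and necroptosis, endothelium, pericytes and smooth muscle, epicardium, atrial myocytes, adipocytes, skeletal muscle, lung, erythroid cells, immediate early genes, mitochondrially encoded mRNAs, sex-linked genes, splicing regulators, and genes with known alternative splicing in heart or wound healing. For each list the called members were counted, over all genes and adjusted over the list alone. The 30 lists with at least 3 measured members were also compared with all other genes by camera in limma, with a preset correlation of 0.01 between genes and the Benjamini-Hochberg correction over the lists. A second run of camera estimated that correlation from the data. Fry, a rotation test, asks whether the genes of a list move on balance in 1 direction and compares them with no other genes. Library measures were compared with two-sided exact permutation tests, whose smallest p with 4 against 4 libraries is 0.029; 30 such tests were run, with Benjamini-Hochberg adjusted values.

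Named genes follow a fixed rule. For MI and for IR they are the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 CPM, a symbol other than a Gm or Rik name, and no overlap between the injured and sham libraries. For the difference of responses and for the sham comparison they are the 10 largest absolute changes by the same filters, without the last. For each list they are up to 4 members with the smallest p in either injury comparison. For usage they are the 10 largest called changes without overlap per injury and any called transcript of the alternative splicing list. For transcripts they are the 5 largest rises and 5 largest falls among called transcripts of genes that were not called. Names outside this rule are said to be chosen after their values were seen. The share of genes with the larger change after MI was computed again with pairs of IR or MISham libraries left out, over the same genes. A few genes that the rule selects are not reported here, but stay in every count, list and test.

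Library totals ran from 24.3 to 63.1 M counts. The tests were run on simulated data with the means, totals and spread of the real libraries and with changes put into the injured group. At each size 66 or 67 of 19741 genes were changed, and as many of the transcripts and shares. Far more were called in the real MI and IR comparisons, so the percentages below do not carry over to those tests. At 2-fold changes they called 64.2% of changed genes for MI, 58.2% for IR and 46.3% for the difference of responses with the MI libraries changed; at 4-fold they called 77.3%, 77.3% and 66.7%. For transcripts they called 46.3% of 2-fold and 68.2% of 4-fold changes in MI. For usage they called 37.3% of changes of 15 points and 83.3% of changes of 30 points in MI, and 22.4% and 51.5% for the difference. At these sizes, and with 4 libraries per group, fewer simulated changes were found in the difference of responses than in the MI response. For genes the same held against the IR response, which was not simulated for transcripts or usage.

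The alternative settings fixed at that time were RLE size factors, library size only, DESeq2 1.42.0, no low-count filter, only the groups compared, the replicate number as a block, a minimum change of 2-fold, an adjusted p under 0.01, other pseudocounts, TPM minimums and share scales, limma's diffSplice, and leaving out each library in turn. Alternatives chosen after seeing the data were MI libraries thinned to the mean MISham total of 26.2 M counts, limma voom with a weight per group, genes without pseudogenes, usage by adjusted p alone, and log2 TPM centred on each library's median. No library was left out of the values reported. In pairs of libraries of 1 group, counts differed by 10.2 to 84.1 times the sampling variance (chi-square per degree of freedom), so none were copies of each other.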

Results

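Gene counts and transcript abundances were compared in mouse heart after 2 kinds of injury, each with its own sham-operated group of 4 libraries. Myocardial infarction (MI) hearts were sampled 72 h after surgery. Ischemia-reperfusion (IR) hearts had 40 min of "LCA", an abbreviation the labels do not explain, and 72 h of reperfusion, the return of blood flow. The MI and MISham samples held tissue of the infarct core and its surroundings, while the IR and IRSham samples held core tissue, so the kind of injury and the region sampled cannot be told apart. The series title asks about alternative splicing in the infarcted heart, and the comparisons below therefore cover genes, transcripts and the share of each gene's annotated TPM held by each transcript. All group values are means of n = 4 libraries.

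Library totals averaged 60.9 ± 2.57 M counts (SD) in MI, 26.2 ± 1.62 in MISham, 29.5 ± 2.37 in IR and 27.3 ± 1.80 in IRSham. The first principal component of log2 CPM held 55.1% of the variance and parted injured from sham libraries. The second held 16.9% and parted the MI and MISham libraries from the IR and IRSham libraries. These differ in injury, in the region sampled and, as given below, in counts of pseudogenes that TPM did not show. Which genes carried the second component was not examined. On the first component, IR replicates 1 and 3 lay at 48.5 and 54.2, nearer to the sham libraries than replicates 2 and 4 at 94.7 and 91.5. The mitochondrially encoded share of counts was 2.42 ± 0.393% in MI against 7.98 ± 0.417% in MISham, and 2.59 ± 0.765% in IR against 7.00 ± 0.227% in IRSham. Averaged over all libraries, Myh6, mt-Nd1, mt-Co1 and Atp2a2 were among the 10 most abundant genes. The 10 most abundant genes of each library, a set that can differ between libraries, held 5.95 ± 0.574% of counts in MI against 14.4 ± 0.759% in MISham. They held 6.78 ± 0.797% in IR against 13.9 ± 0.299% in IRSham. Each of these 4 differences parted all 4 injured from all 4 sham libraries (exact permutation test, two-sided p = 0.0286, the smallest possible; adjusted p = 0.0452 over 30 tests).

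After MI, Sprr1a, a small proline-rich protein of stressed cells, rose from 2.50 ± 3.11 CPM in MISham to 381 ± 82.0 in MI, a log2 fold change of 7.21 ± 0.79 (SE; adjusted p = 2.08e-06). Spp1, the secreted protein osteopontin, rose by 5.86 ± 0.72 (adjusted p = 6.42e-06). Scn4b, a sodium channel beta subunit, fell from 70.6 ± 7.10 to 2.19 ± 0.823 CPM, a log2 change of -5.01 ± 0.61 (adjusted p = 5.95e-06). Kcnip2, an auxiliary subunit of the potassium channels of early repolarization, fell from 326 ± 36.8 to 24.8 ± 10.3 CPM, a change of -3.72 ± 0.58 (adjusted p = 5.97e-05).

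Other large rises after MI were those of Gpnmb, a glycoprotein of macrophages (5.34 ± 0.59), Cemip, a hyaluronan-binding protein (5.28 ± 0.45), Ltbp2, a matrix protein (4.87 ± 0.38), and Ppbp, a platelet chemokine (4.74 ± 0.65). They were followed by Tnc, the matrix protein tenascin C (4.69 ± 0.61), P4ha3, a prolyl hydroxylase subunit of collagen synthesis (4.53 ± 0.41), and Adam8, a membrane protease (4.42 ± 0.58). Other large falls were those of Ces1d, a carboxylesterase (-4.93 ± 0.75), the long noncoding RNA Chaer1 (-4.05 ± 0.42), Mylk4, a myosin light chain kinase (-4.05 ± 0.68), Rpl3l, a ribosomal protein of striated muscle (-3.92 ± 0.49), and Ucp3, a mitochondrial carrier (-3.86 ± 0.66). They were followed by Efnb3, an ephrin (-3.76 ± 0.52), Timp4, an inhibitor of metalloproteinases (-3.75 ± 0.73), and Lgals4, a galectin (-3.69 ± 0.41). These values are log2 fold changes ± SE, and the adjusted p-values of these 15 genes ran from 7.26e-08 (Ltbp2) to 0.000438 (Timp4).

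**Figure D1:**
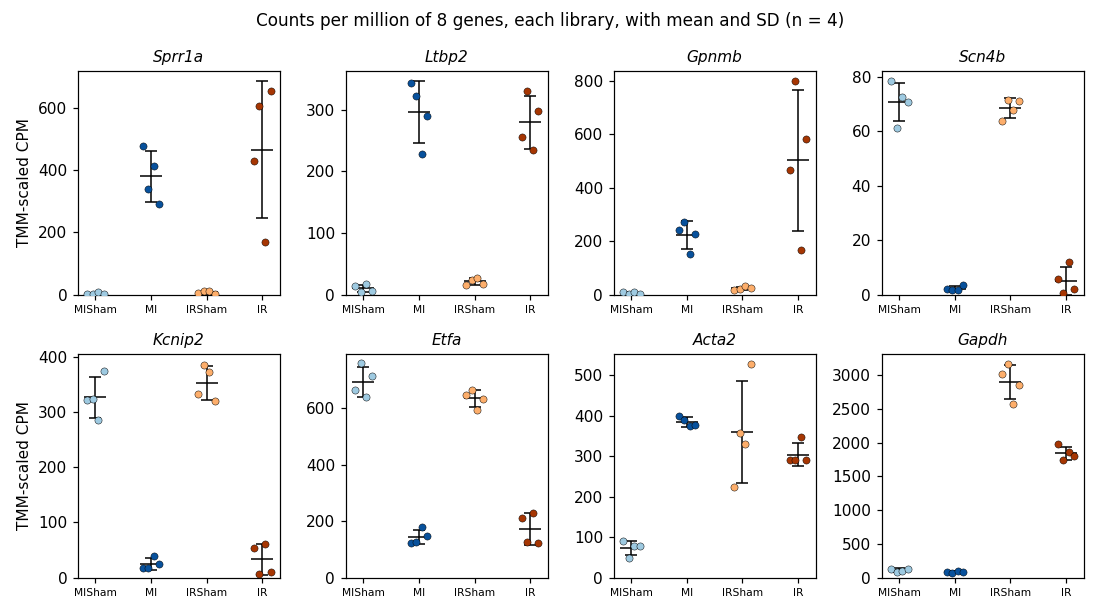
TMM-scaled CPM (vertical axis) of 8 genes in each of the 16 libraries, by group; dots are libraries, bars the mean and SD. Scn4b, Kcnip2 and Etfa were lower in all injured libraries than in all sham libraries, Acta2 averaged 73.6 CPM in MISham against 360 in IRSham, and Gapdh averaged 113 CPM in MISham against 2900 in IRSham.

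All measured members of the main cardiomyocyte lists fell after MI. Lower were 18 of 18 sarcomere genes (Tnnt2 -1.66 ± 0.18, Ttn -1.78 ± 0.18) and 18 of 18 calcium handling and ion channel genes (Ryr2, the calcium release channel, -1.85 ± 0.18; Kcnd2, a potassium channel, -3.09 ± 0.19). So were 24 of 24 fatty acid oxidation genes (Cd36, the fatty acid transporter, -1.87 ± 0.14; Etfa, an electron carrier, -2.26 ± 0.19) and 24 of 24 nuclear-encoded respiratory chain genes (Sdhb -1.94 ± 0.15, Uqcrc2 -1.74 ± 0.14). By camera these 4 lists were lower than other genes, with adjusted p from 3.86e-12 to 4.03e-08; each had adjusted p = 0.358 with an estimated correlation. The 9 measured mitochondrially encoded mRNAs fell as well (mt-Co1 -2.09 ± 0.22, mt-Nd5 -2.14 ± 0.21; camera adjusted p = 0.000419, and adjusted p = 0.38 with an estimated correlation), beside the lower mitochondrial share of counts. Of 14 cardiac stress and fetal genes 12 rose and 0 fell by edgeR's test, among them Nppa, the atrial natriuretic peptide (3.93 ± 0.34), and Ccn2, a matricellular protein (3.40 ± 0.18). Uchl1, a deubiquitinase (2.45 ± 0.15), and Xirp2, an actin-binding protein (1.76 ± 0.17), rose too. For this list camera gave adjusted p = 0.000838, and adjusted p = 0.358 with an estimated correlation.

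Matrix and proliferation genes rose after MI without exception among measured list members. All 24 extracellular matrix and myofibroblast genes rose, among them Bgn, the proteoglycan biglycan (2.26 ± 0.18), Sparc, a matricellular protein (2.10 ± 0.18), Thbs2, thrombospondin 2 (1.46 ± 0.11), and Ltbp2. All 24 cell cycle genes rose, among them Bub1, a mitotic checkpoint kinase (3.40 ± 0.22), Rrm2, a ribonucleotide reductase subunit (3.05 ± 0.23), Birc5, survivin (3.36 ± 0.26) and Mcm6, part of the replicative helicase (2.50 ± 0.19). The camera adjusted p was 2.71e-09 for matrix and 2.07e-10 for cell cycle; each had adjusted p = 0.358 with an estimated correlation. All 12 genes of pyroptosis and necroptosis rose (Ripk3 2.40 ± 0.28, Mlkl 2.00 ± 0.22). So did 12 of 16 apoptosis genes (Apaf1 1.49 ± 0.10, Trp53 1.44 ± 0.12). Of 12 NRF2 response genes 10 rose (Txn1, thioredoxin, 1.17 ± 0.08; Txnrd1, its reductase, 1.22 ± 0.11; Gclm, of glutathione synthesis, 0.94 ± 0.09), while Nqo1, a quinone reductase, fell (-1.42 ± 0.14). MISham replicates 1 and 3 lay above replicates 2 and 4 in the mean log2 CPM of pyroptosis and necroptosis genes (2.71 and 2.51 against 1.82 and 1.94), apoptosis genes (4.26 and 4.19 against 3.86 and 3.93) and NRF2 genes (5.57 and 5.55 against 4.85 and 5.05). All MI libraries lay above all 4 in each. Camera gave adjusted p of 0.00069, 0.00069 and 0.00174 for these 3 lists, and adjusted p = 0.358 with an estimated correlation for each.

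Immune markers rose after MI, from a level that differed among the MISham libraries. MISham replicates 1 and 3 lay above replicates 2 and 4 in the mean log2 CPM of macrophage markers (5.14 and 4.71 against 3.34 and 3.61), neutrophil markers (2.54 and 2.53 against 0.95 and 1.06) and cytokines (2.66 and 2.56 against 0.02 and 1.31). They also did so for matrix genes (6.25 and 6.88 against 4.94 and 5.52) and cell cycle genes (2.84 and 3.45 against 2.12 and 2.15). In each of these 5 lists all MI libraries lay above all MISham libraries. Of 23 monocyte and macrophage markers 19 rose and 2 fell (20 and 2 adjusted over the list alone), with Trem2, a lipid-sensing receptor, at 3.43 ± 0.33 and Cd68, a lysosomal protein, at 3.18 ± 0.33. The 2 that fell, Timd4 (-2.44 ± 0.48) and Lyve1 (-1.09 ± 0.27), are known from resident macrophages and were chosen for naming after their values were seen. Of 11 neutrophil markers 8 rose (Mmp8 3.90 ± 0.38, Mmp9 3.68 ± 0.63, Csf3r 2.23 ± 0.42), and of 17 lymphocyte markers 12 (13 adjusted over the list alone; Gzmb, granzyme B, 3.04 ± 0.60). Of 20 cytokines and chemokines 16 rose (17 adjusted over the list alone; Tgfb1 1.64 ± 0.11, Lif 3.07 ± 0.48, Ccl3 3.13 ± 0.53, Ccl4 2.95 ± 0.42), and of 17 interferon-stimulated genes 10 (Bst2 1.32 ± 0.21, Isg15 1.51 ± 0.39). None of these 4 lists held a fall by edgeR's test. The lymphocyte genes named were scarce, with Gzmb at 1.06 ± 0.229 CPM in MI. Camera called all 5 lists, with adjusted p of 8e-05, 0.0372, 0.0348, 0.00069 and 0.0262 in the order given. None was called with an estimated correlation: in the same order they had adjusted p = 0.519, 0.628, 0.503, 0.519 and 0.703 with an estimated correlation.

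Lists of other cell types went both ways after MI, and camera did not call them. Of 12 resident fibroblast markers 4 rose (Col15a1 2.02 ± 0.13) and 7 fell (Gsn, gelsolin, -2.35 ± 0.15; Scara5 -3.04 ± 0.28; Abca8a -1.43 ± 0.15). Of 16 endothelial markers 6 rose (Pecam1 0.86 ± 0.09, Cdh5 0.78 ± 0.11) and 6 fell (Kdr, a VEGF receptor, -0.75 ± 0.13; Rgcc -1.13 ± 0.11). Of 11 pericyte and smooth muscle markers 5 rose (Pdgfrb 1.04 ± 0.08, Cspg4 1.16 ± 0.09) and 6 fell (Abcc9 -2.29 ± 0.20, Kcnj8 -1.23 ± 0.11). Among 18 measured glycolysis entries, of which 2 carry the symbol Aldoa, 8 rose (Pgam1 1.7 ± 0.15, Eno1 1.61 ± 0.14, Pfkp 1.26 ± 0.11) and 6 fell (Hk2, hexokinase 2, -0.86 ± 0.08). Of 13 hypoxia-inducible genes 4 rose (P4ha1 1.26 ± 0.12, Car9 2.78 ± 0.31) and 4 fell (Egln1, an oxygen sensor, -1.89 ± 0.17; Pdk1, an inhibitor of pyruvate oxidation, -1.23 ± 0.14). Of 15 unfolded protein response genes 10 rose (Pdia6 1.12 ± 0.13, Calr 0.88 ± 0.10, Creld2 0.91 ± 0.12) and 3 fell (Herpud1 -1.76 ± 0.17), or 10 and 4 adjusted over the list alone. Of 13 immediate early genes 8 rose (Egr2 3.15 ± 0.45, Atf3 2.30 ± 0.27, Ier3 1.77 ± 0.18) and 1 fell (Klf4 -0.98 ± 0.15).

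Markers of tissue that could have been taken along with the ventricle were also counted after MI. Of 8 epicardial markers Krt18 rose (2.07 ± 0.50); of 5 measured atrial markers Nr2f2 (0.69 ± 0.10) and Dkk3 (2.01 ± 0.30) rose and Tbx5 fell (-1.88 ± 0.23). The 1 measured adipocyte marker, Lipe, fell (-1.29 ± 0.14), of 6 skeletal muscle markers Tnnt3 (3.45 ± 0.35) and Tnni2 (1.31 ± 0.32) rose, and of 2 lung markers Ager rose (1.81 ± 0.29) and Scgb3a1 fell (-1.18 ± 0.47). Of 5 erythroid markers none passed by edgeR's test (Hbb-bs -0.27 ± 0.53, adjusted p = 0.68). Of 5 sex-linked genes 4 fell (Ddx3y -0.50 ± 0.06, Uty -0.82 ± 0.10), and camera called that list lower (adjusted p = 0.0399; adjusted p = 0.358 with an estimated correlation). Of 53 splicing regulators 27 rose (Ptbp1 1.89 ± 0.15, Ptbp3 1.30 ± 0.09, Hnrnpa1 1.04 ± 0.08) and 15 fell (Rbfox1 -2.83 ± 0.17), or 28 and 15 adjusted over the list alone. Of 60 genes with known alternative splicing 27 rose (Tpm2 2.60 ± 0.14, Actn1 2.73 ± 0.17, Cald1 1.88 ± 0.10) and 27 fell. Adjusted over the list alone, the counts of the MI lists without a second count here were the same as over all genes.

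In all, 6861 genes rose and 5960 fell after MI, 3504 and 3241 of them by at least 2-fold. The fold changes are relative to the TMM scale: with library size alone the median log2 fold change of all genes was 0.393 in MI and 0.323 in IR, and 9318 genes rose and 4270 fell after MI (68.6% higher, against 53.5% with TMM).

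**Figure D2:**
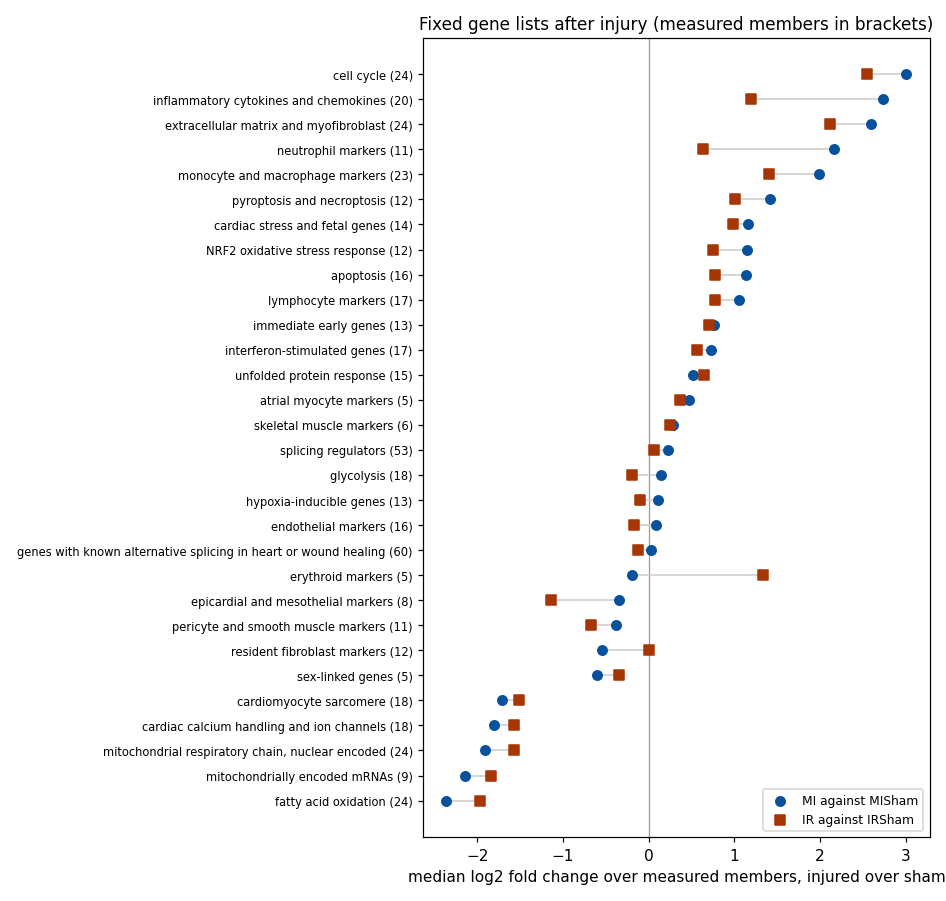
Median log2 fold change (horizontal axis) of the measured members of 30 fixed gene lists after MI (circles) and after IR (squares), each against its own sham group of 4 libraries. The cell cycle median was 3.01 after MI and 2.55 after IR, and the fatty acid oxidation median -2.36 and -1.97.

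After IR, Sprr1a rose from 7.88 ± 4.76 CPM in IRSham to 466 ± 220 in IR, a log2 fold change of 5.89 ± 0.72 (adjusted p = 9.57e-06), and Gpnmb from 23.4 ± 5.31 to 503 ± 264 CPM, a change of 4.42 ± 0.55 (adjusted p = 1.04e-05). Cilp, a cartilage matrix protein also made by cardiac fibroblasts, rose by 3.58 ± 0.41 (adjusted p = 4.65e-06) and Lgals3, galectin 3, by 3.55 ± 0.56 (adjusted p = 9.03e-05). Scn4b fell from 68.4 ± 3.59 to 5.03 ± 5.05 CPM, a change of -3.78 ± 0.58 (adjusted p = 7.37e-05).

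Other large rises after IR were those of Cemip (4.10 ± 0.39), Col8a2, a collagen chain (3.97 ± 0.51), Tnc (3.80 ± 0.59), Ltbp2 (3.72 ± 0.35) and P4ha3 (3.53 ± 0.37). Other large falls were those of Cyp1a1, a cytochrome P450 (-3.74 ± 0.64), Mylk4 (-3.53 ± 0.66), Kcnip2 (-3.40 ± 0.57) and BC023105 (-3.12 ± 0.78). Next came the long noncoding RNA Mhrt, transcribed from the myosin heavy chain locus (-3.07 ± 0.48), Wnk2, a kinase (-3.06 ± 0.47), Smco1 (-3.05 ± 0.40) and Myh7b, a myosin heavy chain (-3.00 ± 0.59). The adjusted p-values of these 13 genes ran from 5.22e-07 (Cemip) to 0.00333 (BC023105), and BC023105 had 23.6 ± 32.6 CPM in IRSham, an SD larger than its mean. The strand setting is not given in the sources used here, so counts of Mhrt cannot be separated from those of genes it overlaps.

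The cardiomyocyte lists also fell as a whole after IR. Lower were 18 of 18 sarcomere genes (Tnnt2 -1.52 ± 0.18, Ttn -1.28 ± 0.18) and 18 of 18 calcium handling and ion channel genes (Ryr2 -1.30 ± 0.18, Kcnd2 -2.48 ± 0.19). So were 24 of 24 fatty acid oxidation genes (Cd36 -1.33 ± 0.14, Etfa -1.88 ± 0.18), 24 of 24 respiratory chain genes (Sdhb -1.55 ± 0.15) and 9 of 9 mitochondrially encoded mRNAs (mt-Co1 -1.77 ± 0.22). The falls were milder in IR replicates 1 and 3 than in 2 and 4, with mean log2 CPM of 10.40 and 10.34 against 9.69 and 9.74 for sarcomere genes and 9.10 and 9.41 against 7.88 and 7.94 for mitochondrially encoded mRNAs. Camera gave adjusted p from 3.62e-12 to 0.000247; each of the 5 lists had adjusted p = 0.411 with an estimated correlation. Of 14 stress and fetal genes 9 rose (Ccn2 2.80 ± 0.18, Nppa 2.58 ± 0.32, Uchl1 2.27 ± 0.15, Xirp2 1.82 ± 0.17). Of the rest 2 fell, Myh7 (-1.46 ± 0.41) and Mt1 (-0.85 ± 0.18), both named here after their values were seen. Myh7 encodes a myosin heavy chain of the fetal heart and Mt1 a metallothionein. Camera gave adjusted p = 0.029 for this list, and adjusted p = 0.411 with an estimated correlation.

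Matrix, proliferation and cell death genes rose after IR. Higher were 22 of 24 extracellular matrix genes (Bgn 2.00 ± 0.18, Sparc 1.64 ± 0.17, Thbs2 1.53 ± 0.11) and 24 of 24 cell cycle genes (Bub1 2.68 ± 0.21, Rrm2 2.63 ± 0.22, Birc5 2.50 ± 0.25). So were 11 of 12 pyroptosis and necroptosis genes (Ripk3 1.83 ± 0.27, Mlkl 1.24 ± 0.22) and 13 of 16 apoptosis genes (Apaf1 1.31 ± 0.10), or 14 adjusted over the list alone. Camera called each, with adjusted p of 1.27e-08, 4.22e-11, 0.00231 and 0.000247; each had adjusted p = 0.411 with an estimated correlation. Of 12 NRF2 response genes 7 rose (Txn1 0.82 ± 0.08, Gclm 0.76 ± 0.09) and Nqo1 fell (-1.22 ± 0.14), with camera adjusted p = 0.01 and adjusted p = 0.411 with an estimated correlation. Of 15 unfolded protein response genes 11 rose (Creld2 1.19 ± 0.12, Pdia6 1.09 ± 0.13) and 2 fell (Herpud1 -1.38 ± 0.17), with camera adjusted p = 0.01 and adjusted p = 0.655 with an estimated correlation.

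Of 23 monocyte and macrophage markers 17 rose after IR (Cd68 2.80 ± 0.32, Trem2 2.72 ± 0.32, Spp1 3.36 ± 0.64) and 2 fell, again Timd4 and Lyve1; camera gave adjusted p = 0.000247, and adjusted p = 0.65 with an estimated correlation. Of 20 cytokines and chemokines 10 rose (Tgfb1 1.29 ± 0.11, Lif 2.37 ± 0.47; camera adjusted p = 0.0364, and adjusted p = 0.734 with an estimated correlation). Of 17 interferon-stimulated genes 10 rose (Bst2 1.07 ± 0.20, Oas1a 1.27 ± 0.37; camera adjusted p = 0.0126, and adjusted p = 0.714 with an estimated correlation). Of 11 neutrophil markers 3 rose (Mmp8 2.85 ± 0.36, Csf3r 1.28 ± 0.41, Mmp9 1.51 ± 0.58) and 1 fell, or 2 and 1 adjusted over the list alone. Of 17 lymphocyte markers 6 rose, or 5 adjusted over the list alone, and camera called neither list. In mean log2 CPM sham and injured libraries overlapped in 3 of these lists. IRSham replicate 4 lay at 3.03 for cytokines, above IR replicate 1 at 2.85, and at 3.03 for neutrophil markers, above 3 of 4 IR libraries. For interferon-stimulated genes IRSham replicate 3 lay at 5.01, also above 3 of 4 IR libraries (replicates 1, 3 and 4 at 5.00, 4.90 and 5.00). In the difference of responses no member of these 5 lists passed edgeR's test over all genes.

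Of 12 resident fibroblast markers 5 rose after IR (Col15a1 1.73 ± 0.12) and 4 fell (Gsn -1.59 ± 0.15, Scara5 -1.53 ± 0.26). Of 16 endothelial markers Pecam1 rose (0.23 ± 0.09) and 8 fell (Kdr -0.93 ± 0.13, Rgcc -1.13 ± 0.11), and of 11 pericyte and smooth muscle markers 5 rose (Pdgfrb 0.72 ± 0.08) and 6 fell (Abcc9 -1.84 ± 0.19). Of 18 glycolysis entries 6 rose (Pgam1 1.24 ± 0.15, Eno1 0.92 ± 0.14) and 9 fell (Hk2 -1.12 ± 0.08). Of 13 hypoxia-inducible genes 2 rose (P4ha1 0.70 ± 0.12, Car9 2.11 ± 0.31) and 5 fell (Egln1 -1.78 ± 0.17), or 4 and 5 adjusted over the list alone. Of 13 immediate early genes 8 rose (Egr2 2.98 ± 0.45) and Klf4 fell (-0.93 ± 0.16). Of 8 epicardial markers Krt18 rose (3.09 ± 0.55) and 3 fell (Upk3b, Wt1 and Lrrn4, with -0.77 ± 0.27 for Wt1). Of 5 atrial markers Dkk3 (2.23 ± 0.30) and Nr2f2 rose and Tbx5 and Kcna5 fell, or 3 and 2 adjusted over the list alone. Lipe fell (-0.94 ± 0.14), Tnnt3 (3.65 ± 0.35) and Tnni2 rose and Atp2a1 fell. Ager rose (0.81 ± 0.27; 1 rise and 1 fall in the lung list adjusted over the list alone) and Alas2 of the erythroid list rose (1.47 ± 0.57, adjusted p = 0.0398; 0 of 5 adjusted over the list alone). Of 5 sex-linked genes 4 fell (Ddx3y -0.35 ± 0.06). Of 53 splicing regulators 21 rose (Ptbp1 1.48 ± 0.15, Ptbp3 1.20 ± 0.09) and 13 fell (Rbfox1 -1.97 ± 0.17), or 22 and 13 adjusted over the list alone. Of 60 genes with known alternative splicing 23 rose and 28 fell, or 24 and 28 adjusted over the list alone. None of these lists was called by camera. For the IR lists without a second count here, the counts adjusted over the list alone were the same.

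In all, 5814 genes rose and 5567 fell after IR, 2581 and 2580 of them by at least 2-fold. With library size alone 8411 rose and 3754 fell (69.1% higher, against 51.1% with TMM).

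Most changes were shared between the injuries. Of the genes that rose after MI, 5238 also rose after IR, where 2021 would be shared by independent sets of that size, and 4901 fell in both, where 1681 would; 16 genes moved in opposite directions. Across the 19741 genes, which are not independent replicates, the MI and IR log2 fold changes had Pearson's r = 0.871 and Spearman's rho = 0.881. No control library was shared between the injuries. Of the 10139 genes changed in the same direction, 75.6% had the larger change after MI, and their median absolute log2 fold change was 1.10 after MI and 0.93 after IR. The size of this share depended on libraries of both groups. IR replicates 1 and 3 had milder falls than IR replicates 2 and 4. Their mean log2 CPM of fatty acid oxidation genes was 6.98 and 7.14, against 5.90 and 6.0, and 6.08 to 6.73 in MI. For sarcomere genes MI replicate 3 was about as mild, at 10.34, against 10.40 and 10.34 in IR replicates 1 and 3. The other MI libraries lay at 9.48 to 9.96 there. Without IR replicates 1 and 3, 56.7% of the same genes had the larger change after MI, 61.4% of those that rose and 51.7% of those that fell. Without IR replicates 2 and 4 it was 83.7%. Without MISham replicates 1 and 3 it was 81.5%, and without MISham replicates 2 and 4 it was 63%. These pairs were chosen after their values were seen, and no MI library was left out in this way.

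**Figure D3:**
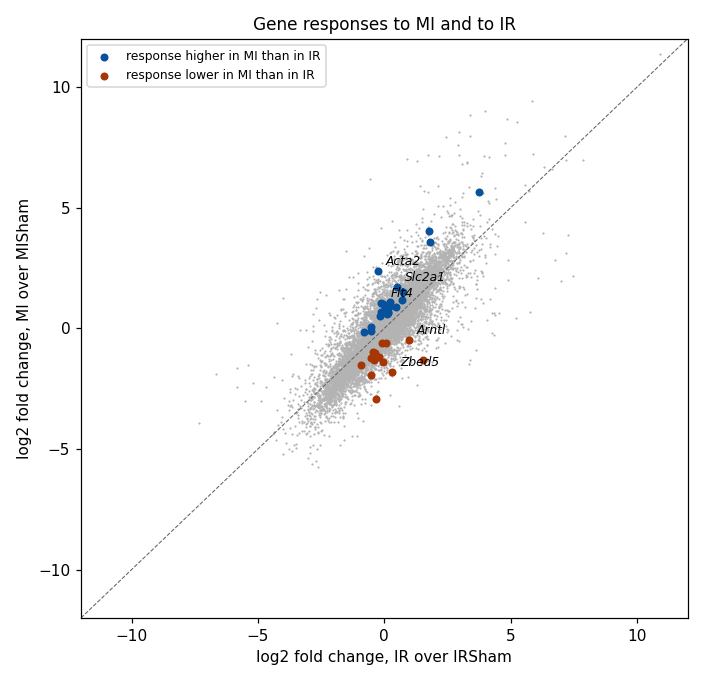
Log2 fold change of each tested gene after MI (vertical axis) and after IR (horizontal axis), each against its own sham group of 4 libraries, without Xist; the dashed line marks equal changes. Coloured points are the 38 genes whose 2 responses differed, 23 higher in MI (blue) and 15 lower (brown).

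The difference of the 2 responses was tested directly, and 23 genes responded more strongly upward, or less strongly downward, to MI than to IR, while 15 did the opposite. Acta2, smooth muscle actin, rose after MI by 2.39 ± 0.22, from 73.6 ± 18.3 to 385 ± 11.6 CPM, and stood at 360 ± 126 in IRSham and 304 ± 29.1 in IR, a difference of responses of 2.63 ± 0.30 (adjusted p = 0.00605). Acta2 was the 1 gene of the matrix list that passed. The difference was 1.20 ± 0.23 for Slc2a1, the glucose transporter GLUT1 (adjusted p = 0.0431). Others were 1.09 ± 0.17 for Flt4, a VEGF receptor of lymphatic endothelium (adjusted p = 0.0245), and 0.85 ± 0.14 for Trib1, a pseudokinase (adjusted p = 0.0245). It was -1.46 ± 0.21 for Arntl, a core gene of the circadian clock (adjusted p = 0.0158). Arntl already differed between the sham groups, by 1.05 ± 0.15 (28.6 ± 4.82 CPM in MISham and 13.8 ± 2.30 in IRSham, adjusted p = 0.00018), and MI over IR was -0.41. The difference was -0.98 ± 0.18 for Slco2b1, an organic anion transporter (adjusted p = 0.0378). Next in size were -0.89 ± 0.15 for Ago4, an Argonaute protein (adjusted p = 0.0309), and -0.87 ± 0.16 for Pnrc1, a nuclear receptor coactivator (adjusted p = 0.0332). Zbed5 had -2.12 ± 0.34 (adjusted p = 0.0245), with 38.8 ± 11.7 CPM in MISham and 3.11 ± 1.02 in IRSham, but its summed TPM was 0.883 ± 0.314 and 0.941 ± 0.440 and the difference there 0.25 (limma adjusted p = 0.62). Of the other 8 named genes, Acta2 (2.65, adjusted p = 0.00203) and Arntl (-1.15, adjusted p = 0.0251) passed limma's test on summed TPM as well. Those of Slc2a1 (1.27, adjusted p = 0.0549), Flt4 (0.98, adjusted p = 0.0565) and Pnrc1 (-0.76, adjusted p = 0.0604) were near their size in counts there and just missed the threshold, while those of Slco2b1 (-0.68, adjusted p = 0.211), Trib1 (0.68, adjusted p = 0.183) and Ago4 (-0.60, adjusted p = 0.111) were smaller than in counts.

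Over all genes, Slc2a1 and Hk1 (0.59 ± 0.11, adjusted p = 0.0332; named after its values were seen) were the 2 glycolysis genes whose responses differed, and 11 of 18 entries were higher adjusted over the list alone. Adjusted over the list alone, 9 of 16 endothelial markers, 6 of 14 stress and fetal genes and 4 of 12 NRF2 genes responded higher in MI, as did 1 gene each of the matrix, hypoxia, pericyte, lung and immediate early lists. By the same adjustment 5 of 12 resident fibroblast markers responded lower in MI, 1 unfolded protein response gene responded higher and 3 lower, 1 sex-linked gene higher and 1 lower, and 5 splicing regulators higher and 2 lower. The other 19 lists held 0 such genes by edgeR's test adjusted over the list alone. Camera called 12 lists higher and 7 lower in the MI response, from glycolysis (adjusted p = 7.67e-09) to hypoxia (adjusted p = 0.0332). None of the 30 lists passed with an estimated correlation, where glycolysis had adjusted p = 0.206 with an estimated correlation. Fry, which compares a list with no other genes, called 3 lists higher in the MI response. These were glycolysis (fry adjusted p = 0.00128), splicing regulators (fry adjusted p = 0.00478) and stress and fetal genes (fry adjusted p = 0.0408).

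The number of genes with a difference of responses was unstable. With RLE size factors 12 were higher and 20 lower (37.5% higher, against 60.5% with TMM), and DESeq2 called 236 and 275 (46.2% higher), which held 37 of the 38. Leaving out 1 library gave 203 higher and 79 lower without IR replicate 3 and 59 and 25 without MISham replicate 3. The higher count was 2, 3, 2, 4, 2, 15, 4, 14, 2, 9 and 14 without MISham replicates 2 and 4, MI replicates 1, 2 and 4, IRSham replicates 1 to 4, and IR replicates 1 and 4 in turn. The lower count was 1, 1, 1, 2, 2, 1, 5, 1 and 7 without MISham replicates 2 and 4, MI replicates 1, 2 and 4, IRSham replicates 2 to 4 and IR replicate 1 in turn.

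MISham was compared with IRSham to see how far the 2 control groups differed before any injury was taken into account. Higher in MISham were 461 genes and lower 171, and 383 of the former were pseudogenes. Rps10-ps2 stood at 39.8 ± 4.22 CPM in MISham and 0.228 ± 0.171 in IRSham, a log2 difference of 7.46 ± 0.30 (adjusted p = 2.12e-10). The other largest were Rpl14-ps1 (6.87 ± 0.31), Vdac3-ps1 (6.48 ± 0.41), Cd63-ps (6.31 ± 0.27), Vcp-rs (6.08 ± 0.27), Ndufab1-ps (4.04 ± 0.57), Mpc1-ps (4.0 ± 0.39), Tpm3-rs7 (3.95 ± 0.26) and Rps12-ps3 (3.85 ± 0.50), all named as copies of other genes. Gapdh, the glycolytic enzyme, had 113 ± 25.6 CPM in MISham and 2900 ± 251 in IRSham, a difference of -4.68 ± 0.17 (adjusted p = 8.07e-12). Its summed TPM was 1892 ± 169 and 2161 ± 323 (log2 difference -0.18, limma adjusted p = 0.547). The injured libraries differed likewise, with Gapdh at 73.2 to 98.9 CPM in MI and 1747 to 1975 in IR. Their summed TPM was 2089 ± 177 and 1989 ± 226. For 54 of the higher pseudogenes the median log2 difference between shams was 3.16 in counts and -0.11 in TPM. For Gapdh and these 54 pseudogenes, the TPM argue against RNA differences of the size seen in counts. How reads shared by near-identical copies were assigned is not given in the sources used here, and why the counts differed was left open.

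Without pseudogenes, 54 genes were higher in MISham and 58 lower (48.2% higher, against 72.9% with them). Of 15 unfolded protein response genes 7 were higher in MISham, or 9 adjusted over the list alone; the examples Manf (1.36 ± 0.18), Hspa5, the chaperone BiP (1.07 ± 0.14), and Creld2 (0.90 ± 0.12) include 2 chosen after their values were seen. Camera gave adjusted p = 1.87e-10 for this list, and adjusted p = 0.391 with an estimated correlation. Of 24 matrix genes 2 were lower in MISham, Acta2 (-2.29 ± 0.22) and Thbs2 (-0.45 ± 0.11), and of 23 macrophage markers Trem2 was lower (-1.29 ± 0.32), or 5 adjusted over the list alone. In mean log2 CPM of macrophage markers, MISham replicates 2 and 4 lay at 3.34 and 3.61, below all IRSham libraries (4.59 to 5.59). MISham replicates 1 and 3, at 5.14 and 4.71, lay within the IRSham range. Camera called 4 lists higher in MISham and 9 lower, and with an estimated correlation it called none of 30. Leaving out MISham replicate 1 raised the number of lower genes from 171 to 328.

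At the transcript level, 40489 transcripts were tested with limma, of which 7569 carried long-read IDs. After MI 19823 were higher and 4081 lower, and after IR 17191 and 3739. The median log2 fold change of all transcripts was 0.604 after MI and 0.48 after IR, so these splits, 82.9% and 82.1% higher, go with the scale. With each library centred on its median, 9136 were higher and 8877 lower after MI (50.7% higher) and 7545 and 8283 after IR (47.7% higher). Quantile normalization gave 9152 and 9106 (50.1% higher) and 7634 and 7932 (49.0% higher). The responses differed for 27 transcripts upward and 7 downward. Between the sham groups 0 transcripts were higher and 8 lower by limma, with 3374 at an unadjusted p under 0.05. Transcripts with long-read IDs held 24.5 ± 0.872% of TPM in MI against 30.4 ± 0.381% in MISham, and 24 ± 1.94% in IR against 30.2 ± 0.823% in IRSham (exact permutation test, two-sided p = 0.0286 for each, adjusted p = 0.0452). Of them 3119 were higher and 995 lower after MI and 2758 and 824 after IR.

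For the difference of responses of transcripts, the upward count was 43, 16, 14, 47 and 73 without MISham replicate 3, IRSham replicates 2 and 4 and IR replicates 1 and 3 in turn. The downward count was 3, 2, 3, 3, 3, 4, 11, 18 and 4 without MISham replicates 1 and 4, MI replicate 4, IRSham replicates 2 to 4 and IR replicates 1, 3 and 4 in turn. Between the sham groups 13 transcripts were lower without MISham replicate 3, and 1 to 4 were higher without MISham replicates 2 and 3, MI replicates 1 to 3, IRSham replicates 1 to 3 or IR replicates 1 and 2.

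Some transcripts changed while the count of their gene did not pass. A Sema4d transcript (ENSMUST00000110039.2) rose from 0.210 ± 0.271 to 12 ± 2.7 TPM after MI (3.42 ± 0.30, adjusted p = 3.15e-07) and from 0.866 ± 0.482 to 12.2 ± 5.62 after IR (2.75 ± 0.30, adjusted p = 4.38e-06). The gene's log2 fold change was 0.10 and -0.08. An Mbnl2 transcript (ENSMUST00000227012.2) of this splicing regulator rose from 0.318 ± 0.595 to 6.70 ± 1.72 TPM after IR (2.61 ± 0.25, adjusted p = 1.52e-06), and a Get4 transcript rose by 2.81 ± 0.52. After MI a Snap23 transcript fell from 8.24 ± 0.653 to 1.52 ± 0.497 TPM (-1.90 ± 0.17, adjusted p = 3.2e-07) and a Grb2 transcript from 11.7 ± 1.76 to 2.65 ± 0.939 (-1.82 ± 0.31, adjusted p = 0.00016). After IR a Mapkapk5 transcript changed by -2.37 ± 0.62 and an Lrrc27 transcript by -2.01 ± 0.42. Other such transcripts had large spreads within a group, among them Hspa8 after MI (163 ± 88.6 TPM), Myh7 (89.7 ± 87.3 in IRSham), and Tagln (28.7 ± 29.8) and Pdlim5 (94.1 ± 63.1) in IR.

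Transcript usage changed in 1015 of 7431 genes after MI, with 735 transcripts gaining and 733 losing share, and in 690 genes after IR, with 464 gaining and 455 losing. For 185 of the MI genes and 164 of the IR genes the gene itself was not called. The shares leave out transcripts with long-read IDs, which held less of all TPM after both injuries. Psap, the precursor of lysosomal saposins, exchanged its main annotated transcript. ENSMUST00000105465.8 went from 26.7 ± 5.83% of the gene's TPM in MISham to 83.1 ± 4.28% in MI, a change of 56.3 ± 3.7 points (SE; adjusted p = 1.96e-06). In IR it went from 35.5 ± 3.97% to 85.4 ± 5.56% (49.9 ± 3.7 points, adjusted p = 1.05e-05), while ENSMUST00000179238.8 lost share (-55.8 points after MI, -48.7 after IR). Which protein form each transcript encodes is not given in the sources used here. Pkm, the pyruvate kinase of glycolysis, shifted toward ENSMUST00000034834.16 by 31.8 ± 3.6 points after MI (23.2 ± 5.94% to 55.0 ± 2.16%, adjusted p = 0.000161) and by 24.9 ± 3.6 after IR (adjusted p = 0.00168). The gene's log2 fold change was 0.14 ± 0.09 after MI (adjusted p = 0.178). Synpo2l, an actin-associated protein of muscle, shifted toward ENSMUST00000119483.2 by 42.1 ± 3.0 points after MI (adjusted p = 5.05e-06) and by 45.4 ± 3.0 after IR (adjusted p = 7.2e-06).

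**Figure D4:**
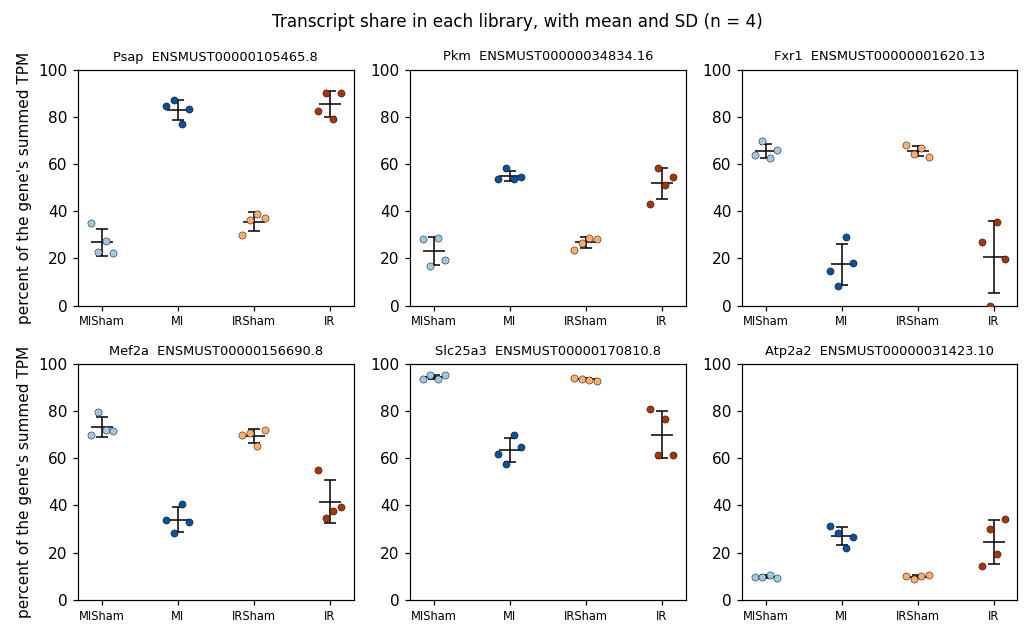
Share of the gene's summed TPM in percent (vertical axis) held by 1 transcript of 6 genes in each of the 16 libraries, by group; dots are libraries, bars the mean and SD. The Psap transcript lay between 77.0 and 87.0% in MI and between 22.2 and 34.8% in MISham; the Slc25a3 transcript lay between 57.7 and 69.8% in MI and at 93.5% or above in MISham.

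Genes with known alternative splicing in heart or wound healing changed usage more often than other genes: 20 of 54 measured (37.0%) against 13.5% of other genes after MI (Fisher's exact test, p = 1.36e-05), and 16 of 54 (29.6%) against 9.10% after IR (p = 1.87e-05). The list and the other genes were not matched for abundance or number of transcripts. A changed mix of cells was not separated from a change of splicing within cells. Fxr1, an RNA-binding protein, lost share of ENSMUST00000001620.13 by 48.0 ± 6.1 points after MI, from 65.5 ± 3.02% to 17.5 ± 8.81% (the share fell by 44.9 ± 6.1 after IR). Mef2a, a muscle transcription factor, exchanged ENSMUST00000156690.8 (-39.3 ± 4.2 points after MI, -27.7 ± 4.2 after IR) for ENSMUST00000107476.8 (34.6 ± 4.3 and 24 ± 4.3). Slc25a3, the mitochondrial phosphate carrier, lost share of ENSMUST00000170810.8 (-30.8 ± 4.0 and -23.4 ± 4.0 points) and gained ENSMUST00000076694.13 (25.1 ± 2.8 and 15.9 ± 2.8). Atp2a2, the calcium pump of the sarcoplasmic reticulum, exchanged ENSMUST00000177974.8 (-18.1 ± 3.8 and -16.1 ± 3.8) for ENSMUST00000031423.10 (17.1 ± 3.6 and 14.6 ± 3.6), while the gene fell by 2.62 and by 2.16 on the log2 scale. For these 2 genes the shifts were milder in the IR libraries with the milder cardiomyocyte falls. The same held for Psap ENSMUST00000105465.8, Pkm ENSMUST00000034834.16 and Fxr1 ENSMUST00000001620.13, but not for Mef2a ENSMUST00000156690.8, and was not tested over all genes. The Atp2a2 share of ENSMUST00000031423.10 was 14.4 and 19.4% in IR replicates 1 and 3 against 30 and 34.1% in 2 and 4, and the Slc25a3 share of ENSMUST00000170810.8 was 80.8 and 76.5% against 61.2 and 61.6%. Of the MI libraries, replicate 3 shifted least in both transcripts, at 21.8% and 69.8%. After both injuries usage also changed in Clta, a clathrin light chain (27.5 ± 3.5 points after MI and 22.6 ± 3.5 after IR for ENSMUST00000170241.8, and the others in the same order), Myl6, a myosin light chain (22.4 ± 4.3 and 16.6 ± 4.3), and Tead1, a transcription factor (21.9 ± 4.2 and 17.2 ± 4.2). It changed likewise in Itgb1, an integrin (18.3 ± 3.3 and 13.3 ± 3.3), Palm (17.5 ± 3.3 and 16.8 ± 3.3), and Camk2d, a calcium-dependent kinase (-17.8 ± 4.1 and -17.1 ± 4.1). The last of these were Sorbs2 (-24.8 ± 3.5 and -13.5 ± 3.5), Macf1 (-13.4 ± 3.8 and -19.6 ± 3.8), and, by different transcripts, Pdlim5.

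Called after MI alone in this list were, among others, transcripts of Tnnt2, Tnc, Nexn, Flna and Pdlim7, and called after IR alone were transcripts of Ldb3 and Bin1; the difference of responses passed for none of them. For Tnnt2, cardiac troponin T, ENSMUST00000189355.7 went from 30.9 ± 8.66% to 74.9 ± 2.04% after MI (44 ± 6.3 points, adjusted p = 0.000875) and changed by -8.7 ± 6.3 points after IR (adjusted p = 0.509). The difference of 52.7 ± 9.0 points had an adjusted p of 0.0809, the smallest of all transcripts. Tnnt2 ENSMUST00000027671.12 changed by -45 ± 5.8 points after MI and 1.5 ± 5.8 after IR (difference -46.5 ± 8.2, adjusted p = 0.0809). Its share was at the floor in MI (2.39e-07%), against 45% in MISham, 40.4% in IRSham and 41.9% in IR. The MI libraries were the deepest and were thinned for gene counts only. An effect of depth on such shares was therefore not tested. Among the largest changes, Fdft1 lost share of ENSMUST00000224267.3, a retained-intron transcript per the annotation, (-62.7 ± 6.8 points after MI, -51.8 ± 6.8 after IR), and Arhgap24 lost share of ENSMUST00000112852.8 (-57.7 ± 7.7 points after MI) while its gene count changed by -0.01 (adjusted p = 0.959). Ano10 exchanged ENSMUST00000216738.2 (-54.7 ± 7.9 points) for ENSMUST00000042546.4 (53.2 ± 8.0) after IR, Ncapd3, of the condensin complex, ENSMUST00000073127.14 (-48.8 ± 8.6) for ENSMUST00000216677.2 (54.0 ± 5.2), and Krt80 lost share of a transcript (-47.3 ± 6.5). For Ddx41 (73.5 ± 17.8 points), Armc2 (-70.9 ± 9.0), Myh7 (70.8 ± 9.6) and Tbc1d10c (-59.7 ± 11.1) after MI, and Unc45a (50.9 ± 9.9) after IR, the share also lay far apart between the sham groups or spread widely within one. The Ddx41 transcript held 0.942 ± 0.610% in MISham and 57.6 ± 37.9% in IRSham, and the Myh7 transcript 7.85 ± 5.41% and 46.4 ± 16.1%. The files do not give how many reads tell such transcripts apart.

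Of the usage changes, 262 gains and 257 losses were shared by MI and IR, where 13 and 13 would be shared by independent sets, and 4 went opposite ways. Across transcripts, which are not independent, the changes in share had Pearson's r = 0.436 and Spearman's rho = 0.387. For the difference of responses limma called 0 transcripts, with 2001 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0809, while diffSplice called 82 gains and 82 losses. Between the sham groups 10 transcripts had the larger and 9 the smaller share in MISham. Without MI replicate 1 the MI counts were 487 gains and 464 losses, and without MI replicate 2 there were 484 losses. The IR gains numbered 290, 263 and 298 without IRSham replicate 1, IR replicate 2 and IR replicate 4, the losses 271 and 286 without IR replicates 2 and 4, and a fit of IR and IRSham alone called 102 and 127. For the difference of responses the gains were 3, 7 and 5 without MI replicate 1 and IR replicates 1 and 4, and the losses 3, 2, 10, 2 and 4 without MISham replicates 1 and 3 and IR replicates 1, 3 and 4. Between the sham groups the larger shares numbered 25, 18, 4, 5, 5, 4, 3, 6, 4, 6, 5 and 4 without MISham replicates 1 and 4, MI replicates 1 to 4, IRSham replicates 1 to 3 and IR replicates 2 to 4. The smaller shares numbered 15, 5, 5, 2, 2, 4, 3, 3, 4, 5, 4 and 3 without MISham replicates 1, 2 and 4, MI replicates 1 to 4, IRSham replicates 1 and 3 and IR replicates 2 to 4.

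The gene counts and the TPM summed by gene were compared as a check of the 2 tables against each other. Across 13623 genes their log2 fold changes had Pearson's r = 0.929 for MI, 0.929 for IR, 0.675 for the difference of responses and 0.448 for the sham groups. Of 8398 genes called in both tables after MI, 7393 changed in the same direction and the others in opposite directions; after IR it was 6534 of 7337. Summed TPM and transcripts were tested without centring, so these counts and the transcript counts below carry the upward shift of the TPM scale. Of 38 genes with a difference of responses in counts, 7 also passed in summed TPM. Among 12856 genes with both, 2472 had a called transcript but no called gene after MI and 2823 after IR, and 396 and 362 genes had transcripts called in opposite directions.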

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

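The depth test and the counts of other splits below were chosen before their results were seen; the other 6 tests and the look at pairs of libraries were chosen after. In 156 groups of 4 libraries, 4 held a library far from the other 3 by Dixon's test (critical value 0.829), and chance flags about 1 in 20 groups. The share of counts in the 10 most abundant genes was 6.8% in MI replicate 3 and 5.6 to 5.8% in the others. The mean log2 CPM of cell cycle genes was 5.00 in IR replicate 1 (others 5.40 to 5.44), of apoptosis genes 4.15 in IRSham replicate 1 (4.23 to 4.24), and of erythroid markers 4.26 in MISham replicate 1 (5.13 to 5.23).

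The responses to MI and IR differed by a direct test for 23 genes upward and 15 downward, and for 27 transcripts upward and 7 downward. Among the genes were Acta2 (2.63), Zbed5 (-2.12), Arntl (-1.46), Slc2a1 (1.20), Flt4 (1.09), Slco2b1 (-0.98), Ago4 (-0.89), Pnrc1 (-0.87) and Trib1 (0.85), as differences of log2 fold changes. Of 100 splits of the libraries 3 gave at least the 38 gene calls of the real one, with 236 in the highest other split and 47 in the next, and 3 of 100 gave at least the 34 transcript calls, with 41 in the highest other. Both shares are under 5%, but this does not exclude chance here. Splits that mix the MI and IR series carry the difference between the series within their groups, and the median over the other splits was 0 calls. With the replicate block the gene calls were 7 and 3. The split with 236 calls exchanged the MI and IR labels of all injured libraries and of 1 pair of sham libraries. For the other sham libraries its contrast adds the difference between the series to that in the injured libraries, instead of subtracting it. Its calls are therefore no measure of chance for the difference of responses, and which genes they were was not examined.

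Of 35 splits for each comparison of 2 groups, the real one alone gave as many calls, so 1 of 35 each. The real and the highest other counts of genes were 12821 and 0 for MI, 11381 and 28 for IR, and 632 and 62 for the sham groups. They were 23904 and 1, 20930 and 12, and 8 and 3 for transcripts, and 1468 and 2, 919 and 14, and 19 and 16 for usage. A rank of 1 in 35 is the best that these splits can give. Other splits also mix the 2 groups and carry any difference between them within their groups, which lowers their counts. The real count lay far above every other split for the MI and IR results and for genes between the sham groups. It lay near the highest other count for transcripts and usage between the sham groups, where chance was not excluded. For usage in the difference of responses, limma called 0 transcripts in the real split (2001 at an unadjusted p under 0.05; diffSplice 82 gains and 82 losses) and up to 21 in others, so all 100 splits reach the real count by construction and the count says nothing about chance. The diffSplice calls were not counted in other splits.

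Pseudogenes and Gapdh differed between the sham groups in counts. For 54 pseudogenes measured in both tables the median log2 difference was 3.16 in counts and -0.11 in TPM (95% bootstrap interval -0.18 to 0), with 0 called in summed TPM by limma, which argues against more pseudogene RNA in the MISham hearts. For the 75 parent genes the median log2 difference was -0.14 in counts and -0.12 in TPM. Their median of counts minus TPM differed by -0.06 from that of 12386 other coding genes, which was 0.06 (permutation p = 1e-05, the smallest that 100000 permutations can give). This is the direction needed if reads shared with copies were counted differently in the 2 series. The shift is small, the permutation takes genes as independent, and the other genes were not matched for length or abundance, so this is weak support. In MI over IR libraries 382 of those 383 pseudogenes were also higher (median 3.97). A different handling of such reads is thus a candidate explanation, and no biological one was tested beyond the first.

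Of 15 circadian clock genes 9 differed between the sham groups, with Arntl, Nfil3, Cry1 and Clock higher and Dbp, Per2, Per3, Nr1d2 and Tef lower in MISham. A different time of day of collection is a candidate explanation: with the 4 genes first noticed left out, 4 morning-phase genes averaged 0.50 and 7 evening-phase genes -0.47, a difference of 0.97 (exact p = 0.00303, the smallest that 330 splits of the genes can give). Genes of 1 clock move together, so this p does not measure the spread between libraries. Leaving out the genes first noticed also does not make the others a fresh test. In the injured libraries the difference was 0.32 (0.01 and -0.31, exact p = 0.109). It left the time of day open, since injury itself moved clock genes (11 called after MI and 12 after IR). Different counting was excluded, since the median absolute log2 difference was 0.72 in TPM and 0.71 in counts, with the same sign for 9 of 9. The labels give no time of collection, and it cannot be told apart from other differences between the series.

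Of genes changed alike by both injuries, 75.6% changed more after MI. Without IR replicates 1 and 3 it was 56.7% of the same genes, and without MISham replicates 2 and 4 it was 63%. IR replicates 1 and 3 had milder falls (fatty acid oxidation mean log2 CPM 6.98 and 7.14, against 5.90 and 6.0 in replicates 2 and 4 and 6.08 to 6.73 in MI). In sarcomere genes MI replicate 3, which was not left out, was about as mild (10.34, against 10.40 and 10.34 in IR replicates 1 and 3). Without the opposite pairs the share was 83.7% (IR replicates 2 and 4) and 81.5% (MISham replicates 1 and 3), so the size of the pattern depends on libraries of both groups. Greater depth was excluded, since with the MI libraries thinned the share was 75.9%. A lower share of cardiomyocytes alone was predicted to move endothelial and resident fibroblast markers alike. In the difference of responses they moved apart by 0.79 ± 0.20 (SE), with 0.32 ± 0.11 for endothelial and -0.47 ± 0.16 for resident fibroblast markers. The prediction thus failed, but the test cannot exclude a lower share as a source of the larger changes. Such markers can respond to injury within their cells, and 4 fibroblast markers rose and 7 fell after MI. The kind of injury and the region sampled were not tested, and the design confounds them.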

How the results depend on the processing

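The thinned libraries, voom, the removal of pseudogenes, usage by adjusted p alone and median-centred TPM were chosen after seeing the data. Counts below are higher and lower (for usage, gains and losses), and the cause was not tested except where a setting tests fewer genes, libraries or smaller effects. For genes, the difference of responses gave 12 higher with RLE, 236 and 275 by DESeq2, 81 and 36 without a low-count filter, 7 and 3 with the replicate block, 7 and 6 at 2-fold or more, 1 and 0 at an adjusted p under 0.01, and 8 lower with MI thinned; without 1 library it ranged from 2 to 203 and from 1 to 79. At 2-fold or more, MI gave 3504 and 3241 and IR 2581 and 2580. Lower in MISham than IRSham were 346 by DESeq2, 52 at 2-fold or more, 75 at an adjusted p under 0.01 and 120 to 328 without 1 library, and without pseudogenes 54 were higher and 58 lower. With an estimated correlation camera called 0 lists higher and 0 lower in each of the 4 comparisons; fry called 17 higher after MI, 10 lower after IR, 3 and 0 in the difference and 1 and 2 between shams. For transcripts, MI gave 9152 and 9106 with quantile normalization, 11330 and 1924 at 2-fold or more and 9136 and 8877 median-centred; IR gave 7634 and 7932, 8321 and 1563, and 7545 and 8283. The difference gave 4 lower at a TPM of 0.1 or more, 4 without a filter and 11 with quantile normalization, 15 and 3 with the block, and 14 to 73 and 2 to 18 without 1 library. Shams gave 5 and 15 with a pseudocount of 0.1, 8 higher with quantile normalization, 1 and 2 in a fit of 2 groups, 5 higher median-centred, and 0 to 4 and 6 to 13 without 1 library. For usage, MI gave 1107 gains by diffSplice, 290 and 301 at 20 points and 487 to 774 and 464 to 768 without 1 library; IR gave 839 and 747, 177 and 186, 102 and 127 in a fit of 2 groups, and 263 to 501 and 271 to 506. The difference gave 2 losses on the arcsine scale, 82 and 82 by diffSplice, 2 gains at a gene TPM of 1, 13 and 9 at 20, 1 loss with the block, and 0 to 7 and 0 to 10 without 1 library. Shams gave 5 losses on the arcsine scale, 21 and 19 by diffSplice, 6 and 5 at a gene TPM of 1, 0 and 0 at 20, 0 and 1 in a fit of 2 groups, 6 and 4 with the block, and 3 to 25 and 2 to 15 without 1 library. Of the values of single genes, Clock after MI reversed to 0.278 with library size only; 396 of 401 stayed on the same side of the threshold by DESeq2, 397 with RLE and 361 with library size only. Of those of single usage changes 52 of 76 did so in a fit of 2 groups and 66 of 77 with the block. The fit of 2 groups does not apply to the difference of responses.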

Other observations

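Replicate numbers carried no sign of pairing between injured and sham libraries. Residual correlations between libraries of the same number ran from -0.056 to 0.051, and 4 of 8 libraries correlated best with their own number (MI replicates 1 and 4, IR replicates 1 and 2). The median SD of log2 CPM within a group was 0.233 in MISham, 0.171 in MI, 0.206 in IRSham and 0.250 in IR. Genes not in the reference annotation held 0.951 ± 0.0507% of counts in MI against 0.724 ± 0.0484% in MISham (exact permutation test, two-sided p = 0.0286), and 0.762 ± 0.0916% in IR against 0.75 ± 0.0733% in IRSham (p = 0.886).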
